A study of Mus musculus with 6 samples.

How the data were processed

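RNA was measured in medial ganglionic eminences (MGE) of mouse embryos at stage E13.5, in 3 control and 3 double-mutant (dmut) samples, each a pool from 3 embryos. Per the labels' protocols, total RNA was purified on columns, messenger RNA was isolated with oligo(dT) beads, and barcoded libraries were made with an Ion Torrent total RNA-seq kit. The submitters' processing notes name the mouse build GRCm38 (mm10). The aligner, the counting program and their versions are not given in the sources used here.

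Per the file headers, the deposited table gave total gene reads, unique gene reads and RPKM for each sample, with group means, quantile-normalised RPKM and a 2-group test, for 17794 genes. The total and unique gene reads were deposited as whole-number counts. Total gene reads also hold reads that match elsewhere. No total gene read count lay between 1 and 9, so a 0 listed there stands for at most 9 reads. The RPKM values deposited by the authors used the total gene reads of each library as their denominator in 199 single-exon genes, with a largest difference of 0.0057 on the log2 scale. The authors' deposited table also held a p-value, an adjusted p-value and a signed fold change for each gene. Their log2 fold followed the ratio of mean RPKM (median absolute deviation 0.0069) more closely than that of total gene reads (0.023). Gene names matched the GENCODE M21 annotation in 97.75% of cases, and this annotation gave biotype, exon length and GC content.

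The main test was edgeR 4.0.16 (R 4.3.3) on total gene reads, with TMM factors, the standard expression filter and the quasi-likelihood test, two-sided, at a Benjamini-Hochberg adjusted p of 0.05. It compared all 3 dmut with all 3 control libraries, without covariates. Levels are TMM-normalised CPM (reads scaled to a fixed library total), given as mean ± SD over 3 libraries, and log2 fold changes are dmut over control with their standard errors. Where a group was listed at 0, a bound on the fold counted each listed 0 as 9 reads per library. Gene lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, adjusted over 35 lists, with camera at an estimated correlation and fry beside it. The groups, the main test, the lists and the rule for named genes were fixed before the data were examined. The rule took Rac1 and Rac3, up to 12 called genes in each direction with groups that did not overlap and symbols that were not predicted or clone names, up to 4 called members of each list (or the 2 of smallest p, as values), and the 3 genes with the largest share of reads. Nkx2-1, Lhx8, Rn7sk, Rmrp, Myo3a, Itga9 and members given as examples of counts over a list alone fall outside this rule and were chosen after their values were seen. A gene, a list and an ontology term that these rules cover are not reported here.

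Total gene reads ranged from 26766556 to 34612095 per library, and 10 reads corresponded to 0.289 to 0.374 CPM by library total, before TMM scaling. No pair of libraries within a group agreed within sampling noise (chi-square per degree of freedom 26.6 to 150), so each counted as its own replicate. The steps were tested on simulated data for the comparison of dmut with control. Over 15141 simulated genes, edgeR recovered 73% of genes changed 2-fold and 96% of those changed 4-fold, with 9 false calls, while DESeq2 recovered 85% and 98% with 83 false calls over 15839 genes. The changes were placed only in genes with many reads. Genes were drawn independently, with the same spread in both groups and no length trend, so these rates need not hold for the real libraries.

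Alternatives fixed at the same stage were other scaling factors, other count filters, DESeq2 1.42.0, limma-voom, the replicate number or the label date as a block, each library left out, other thresholds, and removal of haemoglobin and mitochondrially encoded genes. Alternatives chosen after seeing the data were unique gene reads, limma on log2(RPKM + 1), genes with at least 10 reads in all libraries, protein-coding genes by annotation, removal of each library's trend on exon length and GC content, list medians per library and per scaling, the share of exon reads in named genes, limits of Nkx2-1 and Lhx8 with each library left out, and coding genes matched on abundance to long noncoding RNAs. The trend was fitted without the ribosomal protein, respiratory chain and histone lists. Gene ontology terms in the deposited annotation were also tested after seeing the data.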

Results

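Expression was profiled in the MGE, the ventral forebrain region that gives rise to many cortical interneurons, at stage E13.5. Control embryos were wild type at Rac1 and Rac3, and dmut embryos lacked Rac3 throughout and carried a floxed Rac1 recombined by Cre under Nkx2-1. Each group had 3 libraries, each from a pool of 3 embryos. Control libraries held 33647854, 34612095 and 31881697 total gene reads and dmut libraries 30363369, 29999684 and 26766556. Genes with 10 or more reads numbered 16320, 16315 and 16121 in control and 15479, 15603 and 15301 in dmut, so weakly expressed genes were less often measurable in dmut. The predicted gene Gm26924 took the largest share of reads in every library, from 2.58% to 5.88%, with the highest share in dmut replicate 2, where Lars2 (1.39%) and Arhgap21 (1.07%) came next. Log expression correlated at 0.962 to 0.965 among control libraries, at 0.932 to 0.941 among dmut libraries and at 0.926 to 0.947 between the groups. The titles carry dates: 23 March for control replicate 1, 29 March for control replicate 2 and dmut replicates 1 and 2, and 4 May for replicate 3 of both groups.

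The targeted genes were examined first. Rac3, a small GTPase of neurons (chromosome 11, 120721470 to 120723969), was at 17.7 ± 2.09 CPM in control and 0.193 ± 0.335 CPM in dmut (SD, n = 3 each). Rac3 had 728, 647 and 532 reads in the control libraries, 16 in dmut replicate 1, and was listed at 0 in dmut replicates 2 and 3. With each listed 0 counted as 9 reads, Rac3 was at least 42.3-fold lower (edgeR quasi-likelihood test, adjusted p = 0.0413). Rac3 was not called without control replicate 1, 2 or 3 (adjusted p = 0.218, 0.228 and 0.190), without dmut replicate 3 (0.0681), with limma-voom (0.0632) or with the date as a block (0.375). Rac1, the ubiquitous paralog (chromosome 5, 143505478 to 143528036), was at 272 ± 2.77 CPM in control and 248 ± 26.0 CPM in dmut, a log2 fold of -0.13 ± 0.10 (SE) that did not pass the test (edgeR adjusted p = 0.525). Reads from the remaining exons of a recombined allele and from cells outside the Cre lineage both count toward Rac1, so its level does not check the genotype.

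**Figure D1:**
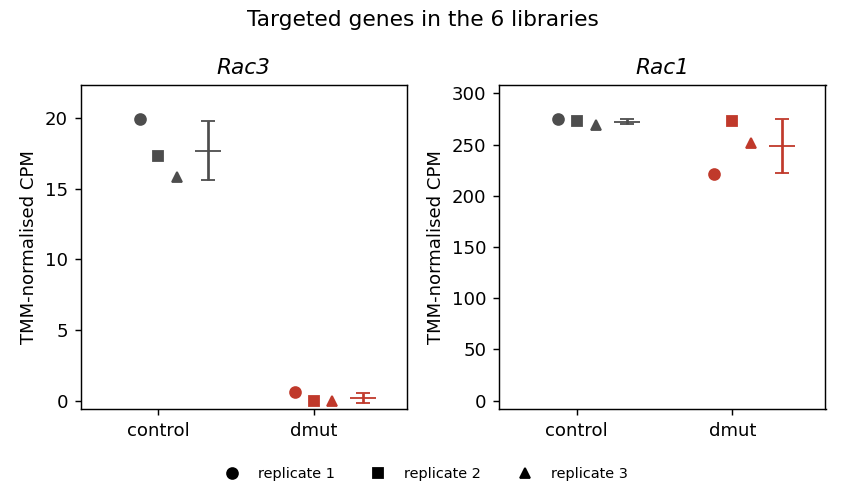
TMM-normalised CPM of Rac3 and Rac1 in the 3 control and 3 dmut libraries. Points are libraries, and the bar beside them is the mean with its SD. Rac3 averaged 17.7 CPM in control and 0.193 CPM in dmut, while Rac1 averaged 272 and 248 CPM.

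Genes of MGE-derived interneurons were among the increases in dmut. Nxph2, a secreted neurexophilin, rose from 0.417 ± 0.0621 to 3.72 ± 1.66 CPM, and Sst, the neuropeptide somatostatin, rose from 17.2 ± 5.04 to 79.3 ± 22.8 CPM (log2 2.20 ± 0.27 SE). Maf, a transcription factor of MGE-derived interneurons, rose by 1.69 ± 0.19 (SE) on the log2 scale. Dynlt1b (1.69) and Dynll1 (0.79), light chains of dynein, and Hspa8 (0.99), a constitutive chaperone, also rose. The other named increases were Hist1h2bc (1.47), Rabac1 (0.97), Rprm (0.93), Zfp428 (0.84) and Ppp1r14b (0.83). Among the decreases, Cmtm1, Slfn3 and the pseudogene Tma7-ps were listed at 0 in all dmut libraries, and their total gene reads were at least 8.54-fold, 6.70-fold and 8.62-fold lower. Exon reads implied by RPKM and the annotated exon length, which is approximate, made up 1.84%, 21.7% and 45.9% of their control reads, so the bounds of Cmtm1 and Slfn3 rest largely on other reads, and for Nxph2 that share was 42.1% in control and 90.4% in dmut. Besides Rac3, further decreases were Snhg11 (-2.57 ± 0.35), Snx14 (-1.84 ± 0.11), Ankrd16 (-1.80), Pisd-ps1 (-1.41), Zkscan5 (-1.35) and Paxbp1 (-1.18). The long noncoding RNAs Xist, which coats the inactive X chromosome, and Miat fell by 1.84 and 1.46.

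Of 15960 genes tested, 77 passed (edgeR quasi-likelihood test, adjusted p of 0.05), 26 higher and 51 lower in dmut, and 3392 had an unadjusted p under 0.05 where chance gives 798. All 77 had groups that did not overlap, against 28.5% of the tested genes and a chance share of 10%. The number of calls was not stable. With the date as a block edgeR called 0 genes, while 2060 of all tested genes had an unadjusted p under 0.05, and the 77 had a median absolute log2 fold of 1.01 (1.05 as reported), a median SE of 0.151 (0.138) and a median of 5.04 degrees of freedom (7.41). Control replicate 1 alone carried its date, so the block left it out of the comparison of dmut with control. The block thus also compared fewer libraries, and its 0 calls do not measure an effect of date. Leaving out control replicate 1, 2 or 3 without the block gave 2, 2 and 4 calls, of which 2, 2 and 2 were among the 77. Leaving out dmut replicate 1, 2 or 3 gave 22, 585 and 12, of which 13, 77 and 7 were among the 77. The share of higher calls also moved: 33.8% as reported, 6.67% of 780 calls with library size alone, which moved the median gene by -0.20, 56.2% of 1783 calls with DESeq2 and 68.2% of the 585 calls without dmut replicate 2. With log2(RPKM + 1) the median gene moved by -0.16. Snx14 was not called from unique gene reads (-0.21, adjusted p = 0.431) nor from log2(RPKM + 1), where it stood at -0.46, and Xist stood at -1.40 with unique reads (adjusted p = 0.0672). Dynlt1b (1.27, adjusted p = 0.0510) and Ppp1r14b (0.86, 0.0588) also lost their calls with unique reads. After removal of the length and GC trend Hist1h2bc (1.18), Rabac1 (0.72), Ppp1r14b (0.53), Zfp428 (0.52), Snhg11 (-2.45), Ankrd16 (-1.74) and Paxbp1 (-1.12) were not called (adjusted p from 0.0598 to 0.0949). With log2(RPKM + 1) this held for Hspa8 (0.79), Rprm (0.70), Zfp428 (0.69), Ppp1r14b (0.63) and Dynll1 (0.57), at adjusted p from 0.0596 to 0.0722.

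The list of MGE-derived interneuron genes was higher in dmut. Of 43 measured members, 4 rose, among them Maf, Sst and Nxph2, none fell and the rest did not pass over all genes. Adjusted over the list alone, 15 rose, among them Npy (log2 1.47), Sp9 (0.70), Nxph1 (1.06) and Erbb4 (0.73), and 1 fell, Gad1 (-0.75), which encodes a GABA-synthesising enzyme. The list median was 0.32 (camera adjusted p = 1.52e-06 at the preset correlation, adjusted p = 0.403 with an estimated correlation, fry adjusted p = 0.0391). Its median relative to the control mean was 0.33, 0.21 and 0.41 in dmut replicates 1, 2 and 3, and the list median was 0.35 with the date as a block, 0.12 with library size alone and 0.11 with log2(RPKM + 1) (camera adjusted p = 3.79e-06). Nkx2-1 and Lhx8 are transcription factors of the MGE. Lhx8 is itself a member of this list and of the cholinergic list. Nkx2-1 stood at 283 ± 28.4 CPM in control and 273 ± 17.2 CPM in dmut, and Lhx8 at 132 ± 14.5 and 130 ± 20.1 CPM, and neither passed.

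**Figure D2:**
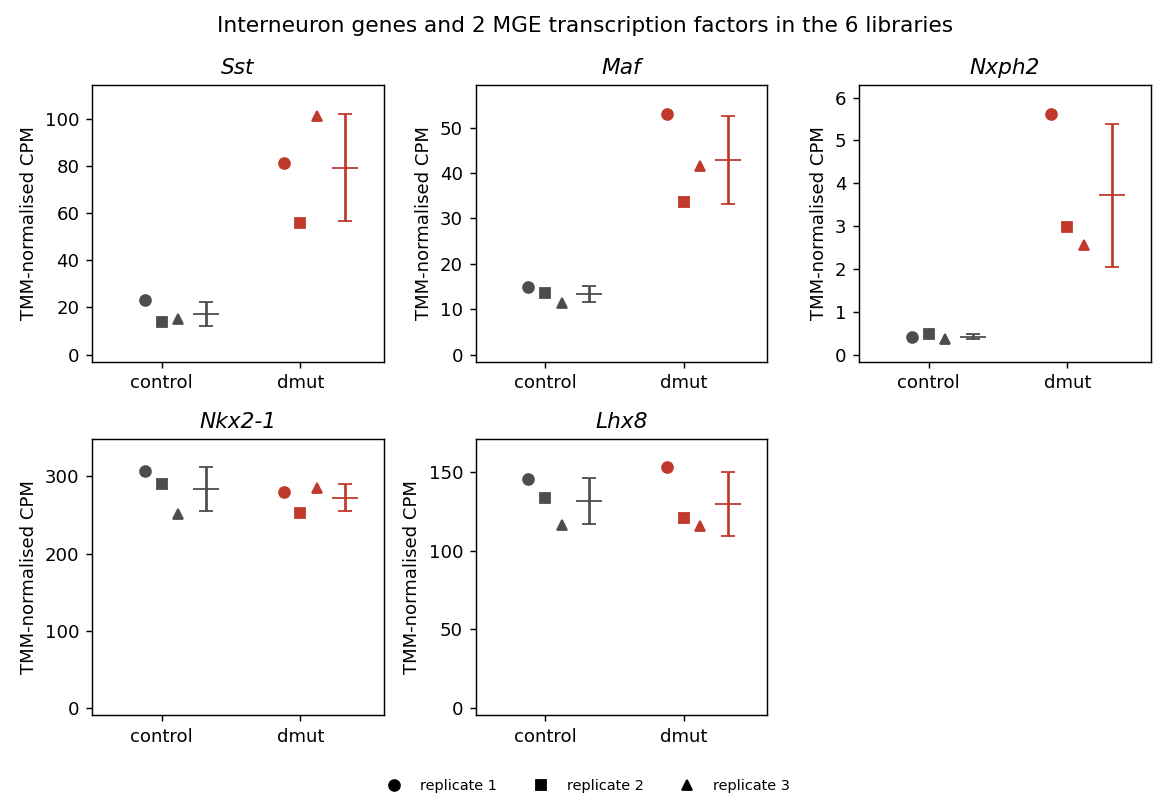
TMM-normalised CPM of Sst, Maf, Nxph2, Nkx2-1 and Lhx8 in the 3 control and 3 dmut libraries, with the mean and SD of each group beside the points. Every dmut library lay above every control library for the first 3 genes, and the groups overlapped for Nkx2-1 and Lhx8.

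Cholinergic and globus pallidus genes were lower as a list. None of the 16 measured members passed over all genes. Adjusted over the list alone 2 fell: Chat, which makes acetylcholine, at 1.50 ± 0.224 CPM in control and listed at 0 in every dmut library (at least 4.50-fold lower in total gene reads, 24.7% of which were exon reads in control by RPKM and annotated length), and Ache (-1.16). The list median was -0.32 (camera adjusted p = 0.0255, adjusted p = 0.403 with an estimated correlation), and the preset call was lost on leaving out control replicate 2 (-0.25, adjusted p = 0.0556), dmut replicate 1 (-0.18, 0.0541) or dmut replicate 3 (-0.31, 0.0931), with a mean of at least 50 reads (-0.28, 0.157) and with log2(RPKM + 1) (-0.33, 0.552), while without dmut replicate 2 the median was -0.68. Markers of neighbouring tissue varied between libraries. Cortical excitatory markers had medians of -1.23, 0.95 and -1.02 relative to the control mean in dmut replicates 1, 2 and 3, against -0.14, -0.04 and 0.21 in control, and septal, preoptic and diencephalic markers -1.19, -0.21 and -1.14 against -0.65, 0.34 and 0.29 in control. Neither list passed (camera adjusted p = 0.201 and 0.0584), nor did LGE and striatal (median -0.01), CGE (-0.12), ventral progenitor (0.12, fry adjusted p = 0.00941) or pan-neuronal genes (0.05).

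Actin regulators were higher as a list relative to the median gene, at a median of -0.02 with library size alone. Of 51 measured members of the Arp2/3 and actin list 1 rose, Tmsb4x, an actin-sequestering peptide (0.74 ± 0.11 SE), and 7 rose adjusted over the list alone, including Arpc3, Ezr and Tmsb10. Tmsb4x was not called after removal of the length and GC trend (0.48, adjusted p = 0.0908) or with log2(RPKM + 1) (0.54, 0.0951). The list median was 0.18 (camera adjusted p = 1.34e-06, adjusted p = 0.326 with an estimated correlation), 0.19, 0.17 and 0.24 in dmut replicates 1, 2 and 3, and 0.01 with log2(RPKM + 1) (camera adjusted p = 0.00431). No member of the Rac regulator list (35 measured, median -0.12), the Rac effector and WAVE list (32, 0.08) or the guidance and migration list (64, -0.08) passed, and none of these lists did. The microtubule list had a median of 0.11 (camera adjusted p = 0.0626).

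Genes of translation, respiration and chromatin were higher as lists. Of 32 histone genes 1 rose, Hist1h2bc, with 21 adjusted over the list alone and a list median of 1.65. None of 67 ribosomal protein genes passed over all genes, although 57 rose adjusted over the list alone (median 0.84), and of 64 nuclear-encoded respiratory chain genes 1 rose, Ndufb10, with 54 over the list alone (median 0.56). Ndufb10, at 0.75, was not called after removal of the length and GC trend (0.43, adjusted p = 0.0872) or with log2(RPKM + 1) (0.55, 0.0664). Among 23 heat shock and chaperone genes Hspa8 rose, with 10 over the list alone (median 0.37, and 0.16 with log2(RPKM + 1)). Camera at the preset correlation called each of these (adjusted p = 3.17e-10, 7.20e-23, 6.50e-24 and 4.73e-06), and with an estimated correlation adjusted p was 0.403, 0.403, 0.403 and 0.326. Fry called only the heat shock list of these (adjusted p = 0.129, 0.139, 0.0865 and 0.00941). Medians in dmut replicates 1, 2 and 3 were 1.77, 2.08 and 0.60 for histones, 1.27, 0.38 and 0.77 for ribosomal protein genes and 0.80, 0.33 and 0.53 for the respiratory chain. The histone median was 1.09 with the date as a block (camera adjusted p = 1.16e-11) and 1.09 without dmut replicate 2, the ribosomal median 0.55 without dmut replicate 1, and the respiratory median 0.33 after removal of the length and GC trend. Of RNAs that lack a poly(A) tail, picked after their values were seen, Rn7sk stood at 1.53, 3.27 and 0.72 and Rmrp at 2.58, 4.61 and -0.82 relative to their control means. Across 10189 genes the log2 fold also fell with exon length (Spearman -0.44, genes not being independent replicates), from a median of 0.79 below 500 bp to -0.14 above 10000 bp. The trend varied between libraries. Deviations from the mean of all libraries correlated with length at 0.10, 0.48 and 0.40 in control replicates 1, 2 and 3. In dmut replicates 1, 2 and 3 the values were -0.38, -0.06 and -0.33.

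**Figure D3:**
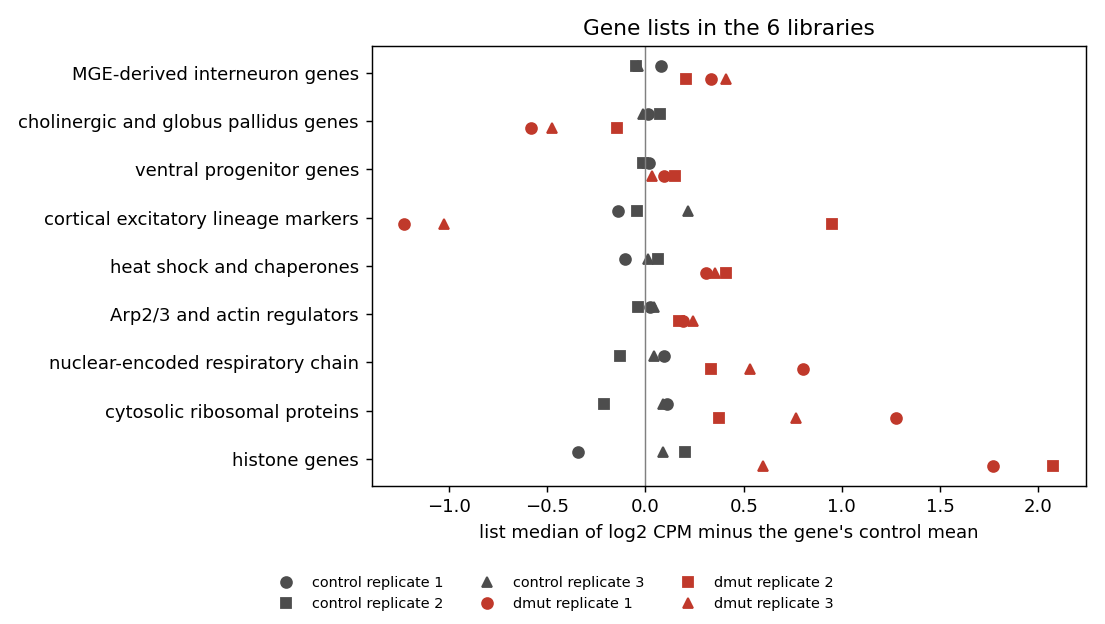
Median over each list of log2 CPM minus the gene's control mean, per library, for 9 gene lists in 3 control (grey) and 3 dmut (red) libraries. Interneuron, heat shock, actin, respiratory and ribosomal lists lay above 0 in all dmut libraries under TMM scaling (the actin list median over the groups was -0.02 with library size alone), histones ranged from 0.60 to 2.08, and cortical markers from -1.23 to 0.95.

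**Figure D4:**
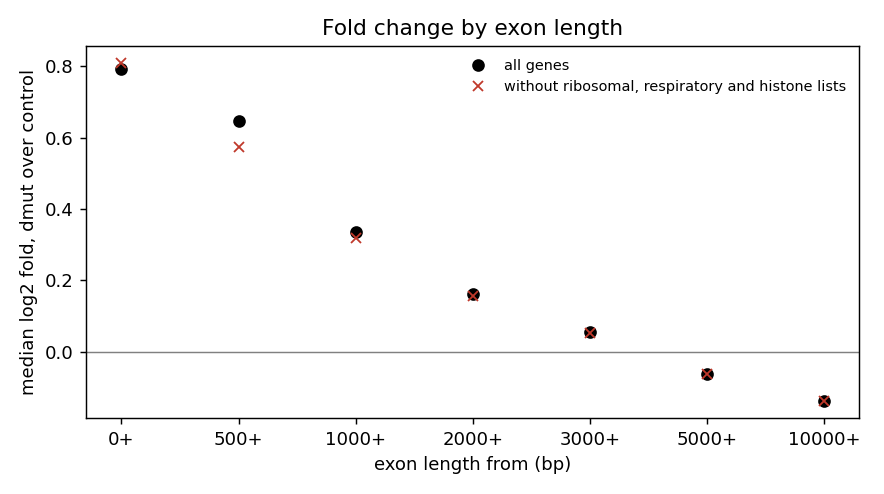
Median log2 fold, dmut over control, of expressed genes in bins of exon length, each bin named by its lower end in bp. Black circles are all genes and red crosses leave out the ribosomal, respiratory and histone lists. Medians run from 0.79 to -0.14.

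Mitochondrially encoded transcripts (median 0.45), hypoxia and glycolysis genes (0.23), G2/M genes (0.11) and microglial markers (0.40) also passed at the preset correlation (camera adjusted p = 0.00477, 0.00759, 0.00477 and 0.0170), with an adjusted p of 0.693, 0.403, 0.737 and 0.719 with an estimated correlation. Positive folds numbered 14 of 15, 24 of 31, 31 of 42 and 21 of 27 members, and no member passed over all genes. Medians in dmut replicates 1, 2 and 3 were 0.95, 0.35 and 0.12 for mitochondrial transcripts (highest control library 0.28). They were 0.15, 0.23 and 0.24 for hypoxia genes (0.06) and 0.26, -0.01 and 0.12 for G2/M genes (0.01). Microglial markers stood at 0.57, 0.287 and 0.10 (0.295). The groups thus overlapped in all but the hypoxia list. Each call was lost in some settings: mitochondrial transcripts without control replicate 3 (median 0.33, adjusted p = 0.0512) or dmut replicate 1 (0.27, 0.275) and after removal of the length and GC trend (0.04, 0.594), hypoxia genes without dmut replicate 2 (0.20, 0.0501) and after that removal (0.17, 0.0589), G2/M genes without dmut replicate 1 (0.06, 0.263) and with log2(RPKM + 1) (-0.06, 0.419), and microglial markers without control replicate 2 (0.27, 0.180) or dmut replicate 1 (0.26, 0.0922) and after that removal (0.13, 0.239). With library size alone the G2/M median was -0.09 and the hypoxia median 0.03, and with log2(RPKM + 1) mitochondrial, hypoxia and microglial medians were 0.22, 0.12 and 0.14. Without dmut replicate 2 the G2/M median was 0.17. Among mitochondrial transcripts mt-Rnr2 was at 0.91 and mt-Nd4l, the 1 negative member, at -0.57, and among microglial markers C1qa was at 1.07 and F13a1 at -1.71. In control, 4, 10 and 4 of the 7530, 6623 and 5207 mt-Nd4l reads were unique. In dmut, 1, 3 and 2 of 3044, 3500 and 3225 were. The mt-Nd4l fold thus rests almost wholly on reads that match elsewhere. The remaining lists did not pass: G1/S genes (median 0.08), cell cycle exit (0.09), p53 and apoptosis (-0.02), erythroid (-0.28), endothelial (0.12), mesenchyme (-0.32), oligodendrocyte precursor (-0.26), choroid plexus (-0.10), immediate early (0.11), interferon response (-0.13), Notch, Wnt and Shh genes (-0.10), Y-linked and X-inactivation genes (0.22) and the targeted genes with their paralogs (0.01). Median and mean differed in sign for p53, pan-neuronal, LGE, choroid plexus, Y-linked and targeted lists.

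The authors' deposited table holds their own test of the same comparison. At their adjusted p of 0.05 it lists 155 genes, 144 higher and 11 lower in dmut, so 92.9% were higher. Of these 155, 151 were tested here and 19 were called, all 19 in the same direction, among them Sst, Hspa8, Dynll1, Dynlt1b, Tmsb4x, Miat and Rac3. All 140 higher calls of the authors' deposited table that were tested here had a positive log2 fold, with a median of 1.28. Both tests used the same libraries, and these calls were picked for being higher in dmut. The shared direction of the 140 and of the 19 is therefore not independent support. The authors' deposited table gives Maf and Nxph2 folds of 3.03 and 7.18 without calling them. Its p-value was 1 for 7671 genes, including 72.1% of the 391 genes with a mean RPKM under 1 and at least 200 reads on average.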

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

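The test of gene reads against exon reads was chosen after seeing the data. In it, 3 genes showed a signal in a quantity that the comparison of total gene reads does not use, the ratio of total gene reads to the exon reads implied by RPKM. This ratio was higher in dmut for Myo3a (1.69 on the log2 scale) and Itga9 (1.50) and lower for Snx14 (-1.43), with at least 1 log2 unit between the groups, whereas over 11124 genes the median difference was -0.02. For Snx14 the total-read fold of -1.84 became -0.21 with unique gene reads. No explanation was tested for these genes.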

How the results depend on the processing

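The alternatives that used unique reads, RPKM, a 10-read minimum, protein-coding genes or the length and GC trend were chosen after seeing the data. Against 77 genes as reported, edgeR called 780 with library size alone, 135 with a mean of at least 50 reads, 401 with at least 10 reads in all libraries, 47 after removal of the length and GC trend, 1065 at an adjusted p of 0.1 and 45 at a log2 fold of at least 1. DESeq2 called 1783 and limma-voom 127. With the replicate block 268 genes were called, 60.8% of them higher. Deviations of libraries with the same number correlated at 0.110, 0.123 and 0.015, and those with different numbers at -0.136 to 0.016. For numbers 1 and 2 the value lay above that range, so a pairing stays open. The main test does not use one. With the date block 0 were called by edgeR, the only tool run with that block, against 2060 at an unadjusted p under 0.05. Control replicate 1 alone carried its date, so this block left it out of the comparison. Leaving out 1 library gave 2 to 585. The cause of these shifts was not tested, beyond the fewer samples or genes that some settings hold. Rac3 stayed lower throughout but lost its call with limma-voom (-8.22), with the date block (-6.61), without control replicate 1 (-6.37), 2 (-6.48) or 3 (-6.54) and without dmut replicate 3 (-5.91), and kept it without dmut replicate 1 (-12.15) or 2 (-5.89). Without dmut replicate 1 every remaining dmut library was listed at 0 for Rac3, so -12.15 is a fitted value without a measured dmut level. The number of lists called went from 11 to 0 with an estimated correlation and to 4 with fry. Fry called the actin, heat shock, interneuron and ventral progenitor lists, the last of which is not among the 11. At the preset correlation camera called 15 lists without dmut replicate 2, 5 of them lower. It called 13 with the replicate block, 3 of them lower, against 1 lower list as reported. Medians of lists that lost the call were, for cholinergic genes, -0.28 with a mean of at least 50 reads, -0.33 with log2(RPKM + 1) and -0.68 to -0.18 over the libraries left out. For G2/M genes they were -0.056 with log2(RPKM + 1), against 0.11 as reported, and 0.062 to 0.17. After removal of the trend, microglial markers stood at 0.13 (0.26 to 0.43 over the libraries left out), hypoxia genes at 0.17 (0.20 to 0.24) and mitochondrial transcripts at 0.044 (0.27 to 0.65). Ttr, not called at 3.83, reversed with limma-voom (-0.35) and without dmut replicate 3 (-1.21), its highest value without a library being 4.42. Of 1638 values of named genes under alternatives, 1357 stayed on their side of the threshold, 171 lost a call, 108 gained one and 2 reversed. Most named genes were not called as reported, and those that stayed uncalled count among the 1357. This share therefore does not measure how stable the calls were. Of 154 values of the 11 called lists, all with camera at the preset correlation, 139 kept the call and 15 lost it. A listed 0 hides up to 9 reads, which limits weakly expressed genes in the shallower dmut libraries.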

Other observations

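Tests of gene ontology terms, of genes near the targeted loci, of poly(A)-lacking RNAs, S phase, MGE tissue share, the date for the interneuron list, sex, the listed nuclear RNAs, the ribosomal list after trend removal and coding genes matched on abundance were chosen after the result was seen. Among 580 terms of 15 to 200 genes, sodium ion transmembrane transport was lower in dmut (54 genes, 44 with a negative fold, median -0.35, camera adjusted p = 0.00902) and after removal of the length and GC trend (median -0.27, adjusted p = 0.0330), with an adjusted p of 0.843 with an estimated correlation. MAPK cascade (40 genes, 34 with a negative fold, median -0.18) passed before that removal (adjusted p = 0.0149, and 0.843 with an estimated correlation) and not after it (adjusted p = 0.0656), where its median of -0.16 was about as large. Messenger RNA splicing (median 0.21), translational initiation (0.27) and the tricarboxylic acid cycle (0.17) were higher before and after. In all, 30 terms were higher and 5 lower, and 0 passed with camera at an estimated correlation. Within 5 Mb of Rac1, 9.35% of 107 genes had an unadjusted p under 0.01 against 8.62% elsewhere, (Fisher p = 0.730), and 1 was called, Zkscan5, 1.70 Mb away. Within 5 Mb of Rac3 the share was 4.23% of 142 genes against 8.66% elsewhere (Fisher p = 0.0695), and edgeR called 0.

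The real grouping of the libraries gave 77 calls and the highest of the other splits gave 4, so 1 of the 10 splits, the real grouping itself, reached 77. With 10 splits the share cannot fall under 0.05. Every other split mixed control and dmut libraries, so a group difference would widen the spread within its groups and lower its calls.

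The lists of ribosomal protein, respiratory chain and histone genes were higher in dmut at the preset correlation (adjusted p = 0.403 for each with an estimated correlation), with 0 of 67, 1 of 64 and 1 of 32 members called over all genes. Removing the trend of other genes on exon length and GC content left ribosomal medians at 0.59 (from 0.84) and histone medians at 1.17 (from 1.65). The length was that of all annotated exons of a gene together (4080 bp for Rps20), which can exceed that of its messenger RNA. The removal can therefore correct these genes too little, and it does not decide whether that trend is the whole cause. The histone median before removal lay above 0.81, the median of genes below 500 bp outside the 3 lists. The respiratory median of 0.33 (from 0.59 over the 63 members with a length and GC value, bootstrap interval over genes 0.281 to 0.388) fell between the bounds set beforehand and also stays open. The G1/S median was 0.081 (bootstrap interval over genes -0.0124 to 0.197). This argues against a rise of G1/S genes as large as that of histones. It does not exclude a smaller rise in the share of S-phase cells, and how histone RNA follows that share was not tested. More RNA without a poly(A) tail may account for the histones: 7 small RNAs had a median of 2.07 (1.95 with listed zeros at their bound), though none of the 7 passed alone and most were near the floor. An effect of genotype was not tested apart from these.

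The list of MGE-derived interneuron genes was higher in dmut at the preset correlation (adjusted p = 0.403 with an estimated correlation), with 4 of 43 members called over all genes. Removing the length and GC trend left the median of the 42 members with a length and GC value at 0.31, before and after. This argues against the trend on annotated length and GC as the whole cause. The date as a block left the median of all 43 at 0.35 (from 0.32, bootstrap interval over genes 0.126 to 0.513, camera adjusted p = 1.73e-06, adjusted p = 0.699 with an estimated correlation, fry adjusted p = 0.267). The median did not shrink with the block, but an interval over genes leaves out the spread between libraries. The block also left out control replicate 1, which alone carried its date. Leaving out that library without the block gave a median of 0.350. The date is therefore not excluded. A larger share of MGE tissue stays open: the upper limit of Nkx2-1 and Lhx8 (log2 fold plus 2 standard errors) was 0.25, inside the interval of the list median (0.135 to 0.430), and above that median without control replicate 1 (0.363 against 0.350), control replicate 2 (0.331 against 0.310) or dmut replicate 3 (0.357 against 0.249), although after trend removal it was 0.106 against an interval of 0.269 to 0.416 (from 0.0257 without dmut replicate 1 to 0.201 without dmut replicate 3, where the interval began at 0.172). Lhx8 is a member of the list it was compared with, so it is not an outside reference. Cortical medians of -1.23 and -1.02 in dmut replicates 1 and 3 went with interneuron medians of 0.33 and 0.41, and 0.95 in replicate 2 with 0.21. Dissection, library preparation and loss of Rac1 and Rac3 stay open, and bulk RNA does not separate a rise per cell from a larger share of cells that express these genes.

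The long noncoding RNAs Xist and Miat were lower in dmut. So was Snhg11, a small nucleolar RNA host gene that the annotation lists as protein coding. The 3 had a median of -1.62 after the length and GC trend was removed (-1.84 before). They were taken from the largest called decreases, and bin medians were only -0.06 from 5000 to 10000 bp and -0.14 above. Removal could hardly have brought them near 0, so it shows only that the fitted trend is smaller than these falls. Fewer female embryos in the dmut pools cannot be told apart for Xist, since the sexes of the pooled embryos are unknown and the Y-linked median was 0.28. A lower yield of nuclear RNA also stays open: 12 other nuclear RNAs had a median of -0.42, but 9 of these were listed after their values had been seen, which voids that test. A test on 821 long noncoding RNAs by biotype, its bound set before its value was seen, gave -0.36 after trend removal, past its bound of -0.25. Coding genes matched on abundance then gave -0.16, a difference of -0.195 (bootstrap interval -0.235 to -0.150, and -0.153 with an interval of -0.195 to -0.0893 for genes of at least 50 reads), so abundance does not account for the whole value, but before trend removal the 2 classes stood at -0.18 and -0.16, a difference of -0.02, which keeps this open.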
